A study of Homo sapiens with 32 samples.

How the data were processed

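RNA from the EPC2 esophageal line was sequenced from monolayers at day 0 and from Matrigel spheroids at day 3 and day 11. Per the labels' protocols, 40000 cells were seeded in a 20 µl Matrigel droplet in keratinocyte serum-free medium with 0.6 mM CaCl2, and IL-13 was given at 20 ng/ml from day 3 to day 11. Total RNA was used, and the labels give 2 independent experiments as batches.

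The authors deposited 1 table of TPM values, with 19345 gene symbols and 32 libraries, rounded to 1 decimal, in which every library sums to nearly the same total. The genome build was hg38, per the submitters' processing notes. The aligner, the quantifier, the annotation and the handling of strand are not given in the sources used here. TPM keeps no depth, so the number of reads is unknown, counting error could not be computed, and precision was taken from the spread between libraries alone. Because TPM divides by the library's own total, a large rise of abundant transcripts lowers all others. A value of exactly 0 can be a failed estimate, since housekeeping genes were listed at 0 in whole groups. No mean, SD or fold is given against a group in which all libraries are listed at 0. Of the symbols, 18162 were found in the gene name table, and coordinates came from GENCODE release 29 on hg38.

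Of the columns, 26 were matched to 1 sample each by name. The 6 IL-13 columns are numbered 1 to 6 and the IL-13 samples 8 to 13, so they were matched to the group only. In the fit each carried the share of its group that belongs to batch 2, 1 of 6, and tests of IL-13 within batch 1, within batch 2 and of the batch interaction were not run. Library numbers in the text are column numbers. Within groups, libraries correlated at r = 0.952 to 0.995 across genes, and no pair shared more than 3.56% equal values among genes with a mean of at least 10 TPM, so none was counted as a duplicate.

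Values were taken as log2(TPM + 1). Genes at 1 TPM or more in at least 6 libraries were kept, which left 12221. All 32 libraries entered 1 fit in limma 3.58.1 (R 4.3.3) with group and batch as terms and an intensity trend, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were D3 spheroid against monolayer, untreated D11 against D3 spheroid, untreated D11 spheroid against monolayer, and IL-13 against untreated D11 spheroid. The interaction of batch with each of the first 3 was tested in a fit with group, batch and their interaction. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation and with fry. These choices, the lists, the rule for named genes and the alternatives, other than those named in the text as chosen later, were fixed before the data were examined.

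The 21 lists held 480 symbols, and 20 lists had at least 3 tested members. They were basal keratinocyte, suprabasal squamous differentiation, cornified envelope and terminal differentiation, proteases and protease inhibitors of squamous epithelium, cell cycle, IL-13 response of esophageal epithelium, IL-4 and IL-13 receptor signalling, desmosomes and tight junctions, epithelial cytokines and chemokines, interferon-stimulated genes, hypoxia and glycolysis, cholesterol biosynthesis, YAP and SRF target genes, partial EMT (epithelial-mesenchymal transition) and wound-edge genes, Notch pathway, unfolded protein and integrated stress response, immediate early genes, mitochondrially encoded transcripts, columnar, goblet and ciliated epithelium, fibroblast, and immune and endothelial. Named genes were, per comparison, the 8 largest rises and 8 largest falls past the threshold with the same sign in both batches, the 2 largest rises and 2 largest falls of each described list, and 22 genes named whatever their result. Results of a few of these genes and 1 part of the culture protocol are not reported here.

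The fit was tested on simulated data with 200 of 12221 genes changed. A log2 change of 0.5 was found for 86.6, 80.6, 83.6, 71.6% in the 4 comparisons above. A change of 1 was found for 98.5, 97.0, 98.5, 98.5%, with 6, 7, 14 and 12 calls among 12021 unchanged. A shift of 1 list was called for it and 0 others with IL-13. The real data held more changes, so no error rate follows. Alternatives covered the pseudocount, the filter, the scaling (median-of-ratios, quantile, mitochondrial genes removed), the batch term, single batches, the libraries entering the fit, library weights and single libraries left out. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.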

Results

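EPC2 is a human esophageal epithelial cell line immortalised with telomerase. RNA was sequenced from EPC2 cells grown flat as a monolayer, taken at day 0 (D0), and from 3D spheroids grown in Matrigel. Spheroids were taken at day 3 (D3) and day 11 (D11), and part of the D11 spheroids had received the type 2 cytokine interleukin 13 (IL-13) at 20 ng/ml from day 3. The groups held 10 D0 libraries, 9 D3 libraries, 7 untreated D11 libraries and 6 D11 libraries with IL-13, 32 in all. The labels place them in 2 independent experiments, batch 1 and batch 2. The comparisons asked how transcript levels differed between monolayer and young spheroid, between young and mature spheroid, and between spheroids with and without IL-13. The values were TPM, a length-normalised share of each library, for 19345 symbols, so depth is unknown and no counting interval is given. Gene list counts were the same adjusted over the list alone, and camera calls held after rescaling by median of ratios (rescaling below), unless stated. Camera used a preset correlation between genes, and its adjusted p with an estimated correlation follows as p if estimated. Levels are mean ± SD over the libraries of a group and the later or treated group comes first. A range that starts at 0 replaces them where a library of the group is listed at 0. Changes are differences of log2(TPM + 1) with their SE and understate the change of low genes. Adjusted p-values use the spread within groups and experiments, pooled over all 32 libraries (D3 also for IL-13), which may be technical.

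On the first 2 principal components of the 12221 genes tested, which held 64.3% and 14.8% of the variance, monolayers, D3 spheroids and D11 spheroids lay apart. Mitochondrially encoded transcripts took 47.6 ± 2.00% of the TPM in monolayers, 47.8 ± 7.27% in D3 spheroids, 21.9 ± 3.98% in untreated D11 spheroids and 21.0 ± 4.75% with IL-13. Keratin transcripts took 3.03 ± 0.296%, 10.3 ± 2.36%, 15.8 ± 2.14% and 14.5 ± 3.14% in the same order. On component 1, D3 library 4 of batch 1 lay at 10.5, near the batch 2 libraries. D3 library 7 of batch 2 lay at -24.5, near the batch 1 libraries. IL-13 library 1 lay at 78.2, and the other 5 IL-13 libraries lay between 49.4 and 56.7. Few markers of other cell types passed the filter. These were 6 of 25 members of the columnar, goblet and ciliated epithelium list, 1 of 12 of the fibroblast list (COL1A1) and 3 of 20 of the immune and endothelial list (CD68, CSF1R and CD14). COL1A1, a fibrillar collagen, measured 5.94 ± 2.41 TPM in monolayers, 19.6 ± 9.37 in D3 spheroids and 69.9 ± 8.43 in untreated D11 spheroids.

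**Figure D1:**
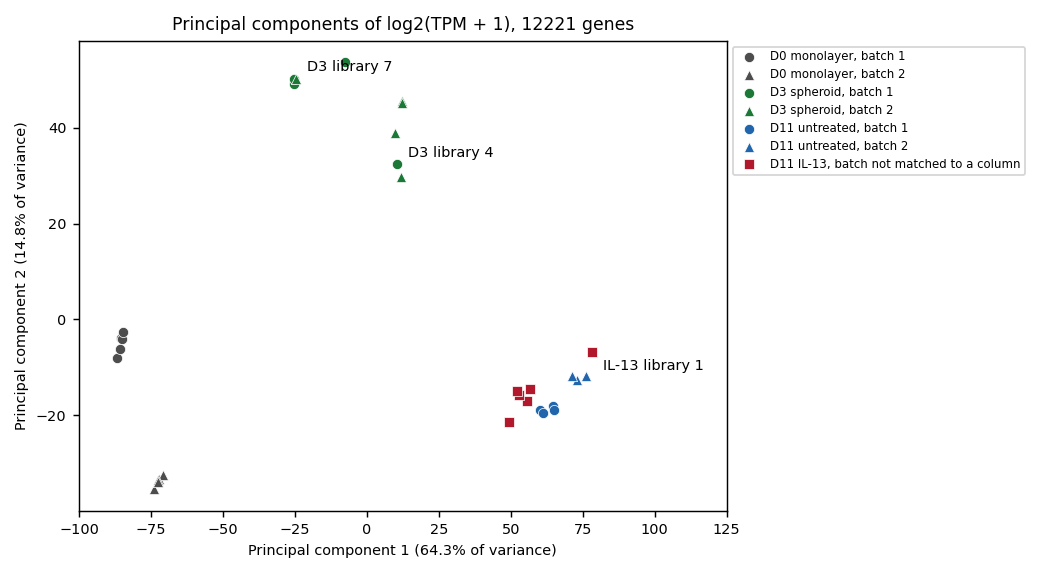
Principal components 1 and 2 of log2(TPM + 1) over the 12221 genes tested, 1 point per library, with colour for the group and shape for the batch. Component 1 held 64.3% of the variance and component 2 held 14.8%, and D3 libraries 4 and 7 and IL-13 library 1 are marked.

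From monolayer to D3, most squamous differentiation genes rose and YAP and SRF targets fell. Monolayers also differed from spheroids in culture conditions, which comparisons with them do not separate from 3D growth. The largest rise was in SPRR1A (2620.3 ± 2219 against 0 to 5.3 TPM, log2 change 9.85 ± 0.57, limma adjusted p = 6.6e-16), a precursor of the cornified envelope at chromosome 1, 152985231 to 152985500 (hg38). The largest fall was in G0S2 (16.0 ± 4.32 against 2977 ± 1083 TPM, log2 change -7.43 ± 0.19, limma adjusted p = 1.5e-24), an inhibitor of lipolysis at chromosome 1, 209675420 to 209676388 (hg38). The basal keratin KRT14 (32835 ± 5824 against 6485 ± 473 TPM, log2 change 2.31 ± 0.092, limma adjusted p = 5.6e-20) rose. Of 12221 genes tested with limma, 1556 were higher and 8339 lower in D3 spheroids (n = 9) than in monolayers (n = 10). At 2-fold or more these were 446 and 1501.

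Of the 32 cornified envelope and terminal differentiation genes tested, 31 rose, 0 fell and 1 did not pass, with 31 and 0 after rescaling. Cornified envelope genes stood above the other genes (median log2 change 2.69, camera adjusted p = 7.7e-24, 0.091 if estimated, medians 1.94 and 3.77 in batches 1 and 2). D3 libraries formed 2 sets, defined after their values were seen, which the means and batch medians mix. SPRR1A lay at 3931 to 4769 TPM in libraries 1, 3, 4, 5 and 6 and 191 to 559.8 in 2, 7, 8 and 9, and the list took 1.37 to 1.54% and 0.116 to 0.278% of the TPM. Large rises were seen in the alarmin S100A8 (1764 ± 1297 against 0 to 11.7 TPM, log2 change 8.21 ± 0.42) and the small proline-rich SPRR1B (2251 ± 1675 against 10.1 ± 5.21 TPM, log2 change 7.12 ± 0.37), with a limma adjusted p of 4.0e-17 or less. SPRR3 (222 ± 184 against 0 to 0.7 TPM, log2 change 6.79 ± 0.44) and the elastase inhibitor PI3 (417 ± 317 against 0 to 0.9 TPM, log2 change 7.62 ± 0.39) followed, with a limma adjusted p of 1.1e-14 or less. The stress keratin KRT16 (4329 ± 2913 against 13.9 ± 7.49 TPM, log2 change 7.85 ± 0.32), the growth factor-binding IGFBP3 (448 ± 351 against 1.41 ± 0.595 TPM, log2 change 6.77 ± 0.45) and the creatine kinase CKB (378 ± 163 against 3.04 ± 1.44 TPM, log2 change 6.46 ± 0.21) rose as well, with a limma adjusted p of 2.5e-14 or less. Of the 26 suprabasal squamous differentiation genes tested, 18 rose, 2 fell and 6 did not pass, with 19 and 0 after rescaling. Suprabasal genes stood above the other genes (median log2 change 1.08, camera adjusted p = 2.5e-16, 0.062 if estimated). The largest rises were in the esophageal keratins KRT4 (71.9 ± 45.5 TPM, listed at 0 in all 10 monolayer libraries) and KRT13 (67.1 ± 34.6 against 0 to 0.4 TPM, log2 change 5.72 ± 0.25), with a limma adjusted p of 1.1e-17 or less. Of members that fell, EMP1 (48.3 ± 4.24 against 75.8 ± 11.8 TPM, log2 change -0.62 ± 0.087, limma adjusted p = 1.8e-07) stood at -0.080 after rescaling and did not pass. ANXA1 (132 ± 20.5 against 148 ± 7.09 TPM, log2 change -0.18 ± 0.075, limma adjusted p = 0.03) stood at 0.36 after that rescaling and 0.12 after quantile normalization, and did not pass in batch 2 alone, without D3 libraries 4 and 7, or without any 1 of monolayer library 1 or D3 libraries 7, 8 or 9 (-0.17 to -0.13).

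Of the 24 desmosome and tight junction genes tested, 13 rose, 9 fell and 2 did not pass, with 17 and 5 after rescaling. Junction genes stood above the other genes (median log2 change 0.21, camera adjusted p = 5.6e-05, 0.17 if estimated, medians 0.10 and 0.28 in batches 1 and 2). Rises were led by DSG1 (14.0 ± 10.4 TPM, listed at 0 in all 10 monolayer libraries), a desmosomal cadherin, and plakophilin PKP1 (335 ± 107 against 63.7 ± 2.19 TPM, log2 change 2.30 ± 0.12), with a limma adjusted p of 6.5e-11 or less. Falls were led by the claudins CLDN23 (0.778 ± 0.353 against 4.12 ± 1.75 TPM, log2 change -1.49 ± 0.18) and CLDN12 (2.67 ± 0.274 against 8.61 ± 1.70 TPM, log2 change -1.38 ± 0.083), with a limma adjusted p of 1.4e-08 or less. Of the 18 basal keratinocyte genes tested, 5 rose, 11 fell and 2 did not pass, with 7 and 9 after rescaling. Basal genes were not separated from the other genes (median log2 change -0.57, camera adjusted p = 0.54, 0.80 if estimated). KRT15 (431 ± 39.6 against 29.1 ± 11.8 TPM, log2 change 3.97 ± 0.13) rose with KRT14, with a limma adjusted p of 5.6e-20 or less. The laminin chain LAMB3 (95.8 ± 20.2 against 768 ± 333 TPM, log2 change -2.91 ± 0.15, limma adjusted p = 3.7e-17) fell.

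Of the 18 YAP and SRF target genes tested, 0 rose, 18 fell and 0 did not pass, with 0 and 17 after rescaling. YAP and SRF target genes stood below the other genes (median log2 change -1.36, camera adjusted p = 1.9e-06, 0.035 if estimated). They were led by CCN2 (1.42 ± 0.338 against 179 ± 65.0 TPM, log2 change -6.16 ± 0.15), a matricellular growth factor, and thrombospondin THBS1 (101 ± 30.4 against 3369.5 ± 429 TPM, log2 change -5.10 ± 0.13). Fibronectin FN1 (7.66 ± 0.763 against 1062 ± 466 TPM, log2 change -6.84 ± 0.15) was also among the largest falls. So were the activin antagonist FST (25.2 ± 6.47 against 965 ± 281 TPM, log2 change -5.18 ± 0.15) and tissue factor F3 (25.1 ± 4.19 against 667 ± 126 TPM, log2 change -4.67 ± 0.10), all 5 with a limma adjusted p of 1.7e-23 or less. Of the 20 interferon-stimulated genes tested, 0 rose, 20 fell and 0 did not pass, with 0 and 19 after rescaling. Interferon-stimulated genes stood below the other genes (median log2 change -1.81, camera adjusted p = 0.026, 0.80 if estimated, medians -0.86 and -2.76 in batches 1 and 2). The change differed between batches for 19 of 20. CXCL10 (0 to 0.7 against 18.2 ± 18.2 TPM, log2 change -2.92 ± 0.46) and IFI6 (6.18 ± 2.49 against 58.2 ± 44.2 TPM, log2 change -2.68 ± 0.31) fell most, with a limma adjusted p of 1.1e-06 or less. Of the 19 unfolded protein and integrated stress response genes tested, 0 rose, 18 fell and 1 did not pass, with 0 and 16 after rescaling. Stress response genes stood below the other genes (median log2 change -1.70, camera adjusted p = 0.019, 0.80 if estimated, medians -1.15 and -2.29 in batches 1 and 2). Examples were PPP1R15A (71.8 ± 30.5 against 881 ± 688 TPM, log2 change -3.19 ± 0.29, limma adjusted p = 1.9e-11), a subunit of the phosphatase of eIF2 alpha, and CHAC1, a glutathione-degrading enzyme. CHAC1 (35.3 ± 60.7 against 146 ± 129.9 TPM, log2 change -2.86 ± 0.70, limma adjusted p = 4.6e-04) stood at -1.003 in batch 1 alone and did not pass there. D3 libraries 4 (135.8 TPM) and 5 (148.6 TPM) set its D3 mean, which was 22.7 and 21.1 TPM without each.

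Of the 22 epithelial cytokines and chemokines tested, 4 rose, 12 fell and 6 did not pass, with 7 and 11 after rescaling. Cytokine genes were not separated from the other genes (median log2 change -0.97, camera adjusted p = 0.74, 0.90 if estimated, medians -0.50 and -1.72 in batches 1 and 2). The neutrophil growth factor CSF3 (13.0 ± 13.8 against 506 ± 124 TPM, log2 change -5.67 ± 0.39) and TNF (3.44 ± 3.30 against 147 ± 105 TPM, log2 change -4.99 ± 0.33) fell most, with a limma adjusted p of 4.8e-14 or less. The chemokine CXCL14 (57.6 ± 22.8 against 0 to 0.2 TPM, log2 change 5.71 ± 0.17) and the interleukin 36 antagonist IL36RN (7.59 ± 5.59 against 0 to 0.1 TPM, log2 change 2.65 ± 0.28) rose most, with a limma adjusted p of 8.9e-10 or less.

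Of the other genes fixed for every comparison, KRT5 (37339.6 ± 5999.9 against 13755 ± 1427 TPM, log2 change 1.43 ± 0.087) and the envelope genes IVL (22.8 ± 17.5 against 0 to 1.4 TPM, log2 change 3.33 ± 0.37) and FLG (1.13 ± 0.505 against 0 to 0.2 TPM, log2 change 0.96 ± 0.11) were higher, with a limma adjusted p of 6.2e-09 or less. So were CRNN (13.4 ± 10.1 TPM, listed at 0 in all 10 monolayer libraries) and the protease inhibitor SPINK7 (0 to 3.6 against 0 to 0.4 TPM, log2 change 1.02 ± 0.21), with a limma adjusted p of 6.0e-05 or less. The proliferation marker MKI67 (74.2 ± 28.2 against 177 ± 53.8 TPM, log2 change -1.24 ± 0.18) and the chloride channel ANO1 (1.61 ± 0.267 against 9.12 ± 4.05 TPM, log2 change -1.83 ± 0.15) were lower, with a limma adjusted p of 1.9e-07 or less. Receptor chains IL4R (10.1 ± 1.23 against 36.6 ± 4.53 TPM, log2 change -1.77 ± 0.075) and IL13RA2 (0 to 0.1 against 1.08 ± 0.379 TPM, log2 change -1.01 ± 0.072) were too, with a limma adjusted p of 9.8e-14 or less. The basal transcription factor TP63 (18.0 ± 1.90 against 21.2 ± 4.37 TPM, log2 change -0.22 ± 0.091, limma adjusted p = 0.029) was called lower, but not without the batch term, with mitochondrial genes removed or without any 1 of monolayer libraries 4, 8, 9 or 10 or D3 libraries 3 or 7 (-0.20 to -0.18). It stood at 0.30 under median-of-ratios scaling, 0.25 under quantile scaling and 0.047 in batch 1 alone. The cytokine suppressor SOCS1 (49.0 ± 14.2 against 69.0 ± 9.60 TPM, log2 change -0.53 ± 0.13, limma adjusted p = 4.3e-04) was lower as deposited and stood at 0.0060 after rescaling. It did not pass after quantile normalization or in batch 2 alone. CISH (16.2 ± 1.86 against 17.3 ± 2.19 TPM, log2 change -0.087 ± 0.094, limma adjusted p = 0.40) did not pass as deposited. It stood at 0.42 and 0.39 under those scalings and at -0.24 in batch 1 alone, and passed in all 3. TSLP (0.600 ± 0.433 against 0 to 5 TPM, log2 change -0.63 ± 0.30, limma adjusted p = 0.055) did not pass, but did in batch 2 alone (-1.53), with a pseudocount of 5 and without any 1 of monolayer libraries 1, 2, 3, 5 or 7 or D3 library 4 (-0.74 to -0.70). CAPN14 (0.144 ± 0.0527 against 0.120 ± 0.0422 TPM, log2 change 0.032 ± 0.083, limma adjusted p = 0.73) did not pass. CCL26 was listed at 0 in all 10 libraries of monolayers and at 0 to 0.1 TPM in D3 spheroids. ALOX15 lay at 0 to 0.2 TPM and 0 to 0.2 TPM, and neither was tested.

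The split of calls depended on the scaling. Median-of-ratios rescaling shifted the median log2 change of all genes by 0.43, from -0.44 to -0.0052. It gave 4064 genes higher and 4052 lower, with 5606 calls in the same direction and 854 reversed. Quantile normalization gave 3706 higher and 4421 lower. The calls numbered 1355 higher and 8310 lower in batch 1 and 1901 and 7744 in batch 2. The change differed between batches for 4430 genes. The libraries of both groups did not overlap for 5418 of 12221 genes, against 0.00217% by chance. Of the named genes that passed they overlapped for ANXA1, CHAC1, CXCL10, MKI67, SOCS1, SPINK7 and TP63. Small proline-rich, late cornified envelope, SERPINB and keratin genes have close paralogs, so values of single members are uncertain.

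Other lists above the remaining genes in D3 spheroids were proteases and protease inhibitors (22 rose and 1 fell of 26, camera adjusted p = 2.5e-21, 0.057 if estimated, medians 1.00 and 1.81 in batches 1 and 2) and hypoxia and glycolysis genes (12 rose and 5 fell of 24, 17 and 3 after rescaling, camera adjusted p = 4.9e-06, 0.37 if estimated, medians -0.067 and 0.59 in batches 1 and 2). Immune and endothelial markers (2 rose and 1 fell of 3, camera adjusted p = 0.018, 0.062 if estimated, medians 0.56 and 1.04 in batches 1 and 2) were another. The Notch pathway list also ranked above (6 rose and 10 fell of 19, camera adjusted p = 0.019, 0.37 if estimated, camera adjusted p = 0.20 after rescaling, medians 0.10 and -0.35 in batches 1 and 2), although its median log2 change was -0.17 and its mean 0.23. Of its genes 10 rose and 6 fell after rescaling. Not separated were cell cycle genes (0 rose and 22 fell of 30, 1 and 5 after rescaling, camera adjusted p = 0.90, 0.98 if estimated, medians -1.17 and -0.17 in batches 1 and 2) and cholesterol biosynthesis genes (0 rose and 19 fell of 23, 5 and 7 after rescaling, camera adjusted p = 0.17, 0.80 if estimated, medians -1.01 and -0.33 in batches 1 and 2). Partial EMT (epithelial-mesenchymal transition) and wound-edge genes (6 rose and 13 fell of 21, camera adjusted p = 0.58, 0.80 if estimated, camera adjusted p = 0.0065 and below the other genes after rescaling) were another. Adjusted over the list alone, 20 cell cycle genes fell.

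**Figure D2:**
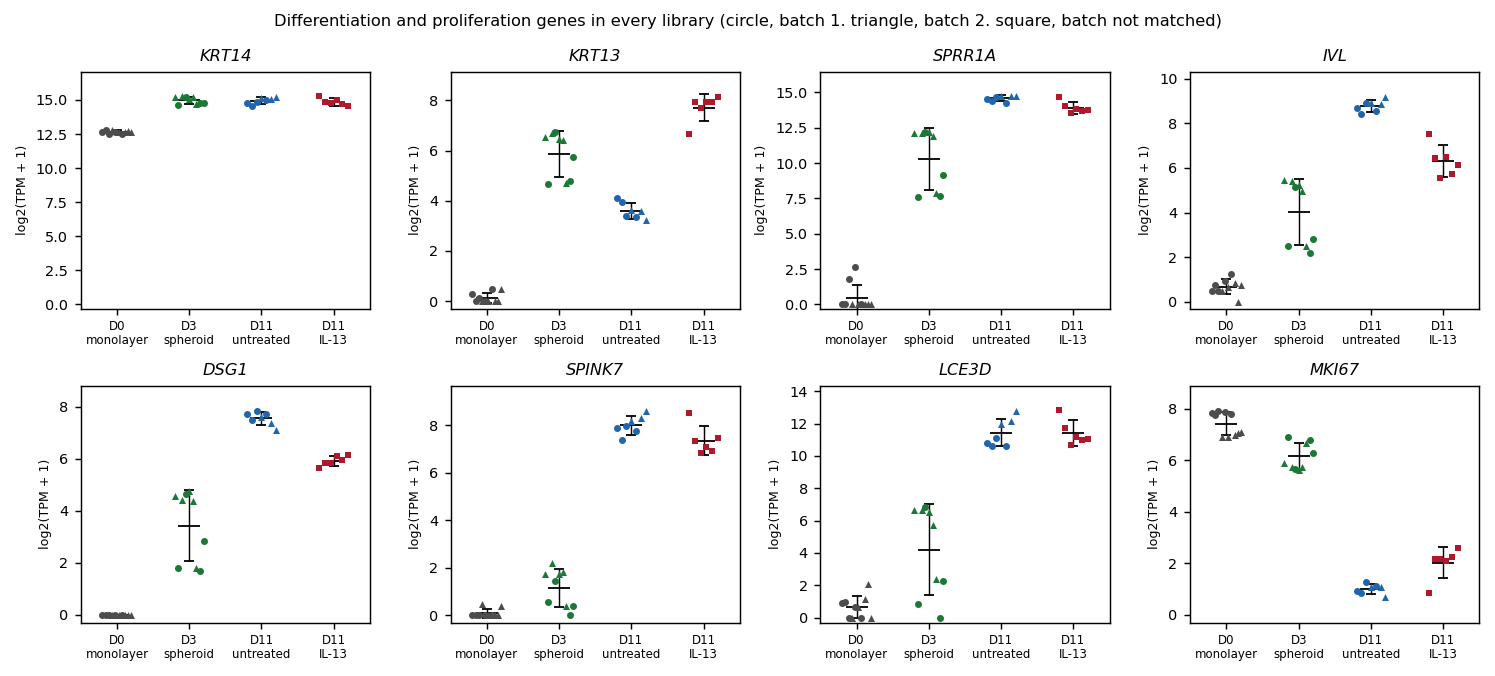
Log2(TPM + 1) of 8 differentiation and proliferation genes in each library of the 4 groups, 1 point per library (circles batch 1, triangles batch 2, squares IL-13 libraries whose batch was not matched), with the mean ± SD as a bar. IVL, DSG1, SPINK7 and LCE3D were higher at D11 than at D3, while MKI67 was lower (1.01 ± 0.267 TPM in 7 untreated D11 libraries).

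Between D3 and D11, 32 of 32 cornified envelope, 22 of 24 hypoxia and 20 of 21 wound-edge genes rose in untreated spheroids. Of 30 cell cycle genes 29 fell. Of these list calls only that of wound-edge genes held with an estimated correlation. The largest rise was in LCE3E (1861 ± 966 against 0 to 31.6 TPM, log2 change 8.14 ± 0.60, limma adjusted p = 3.8e-13), a late cornified envelope protein. The largest fall was in MKI67 (1.01 ± 0.267 against 74.2 ± 28.2 TPM, log2 change -5.21 ± 0.19, limma adjusted p = 4.4e-20), a proliferation marker. Of 12221 genes, 4102 were higher and 4370 lower in untreated D11 spheroids (n = 7) than in D3 spheroids (n = 9), 1058 and 900 of them at 2-fold or more.

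Of the 32 cornified envelope and terminal differentiation genes tested, 32 rose, 0 fell and 0 did not pass, with 32 and 0 after rescaling and 31 and 0 with mitochondrial genes removed. Envelope genes stood above the other genes (median log2 change 4.36, camera adjusted p = 5.0e-12, 0.30 if estimated). Leading rises were LCE3D (3272 ± 2071 against 0 to 112 TPM, log2 change 7.44 ± 0.71), at chromosome 1, 152579381 to 152580504 (hg38), and LCE3A (891 ± 486 against 0 to 45.3 TPM, log2 change 6.74 ± 0.71), with a limma adjusted p of 1.0e-09 or less. SPRR2D (2749 ± 921 against 53.4 ± 43.5 TPM, log2 change 6.52 ± 0.57), CRCT1 (2749 ± 1543 against 49.7 ± 46.6 TPM, log2 change 6.83 ± 0.58) and SLURP1 (1021 ± 127 against 25.1 ± 21.7 TPM, log2 change 6.19 ± 0.48), a secreted Ly6 protein, followed with a limma adjusted p of 1.6e-11 or less. Of the 26 squamous proteases and protease inhibitors tested, 23 rose, 2 fell and 1 did not pass, with 23 and 2 after rescaling and 22 and 2 with mitochondrial genes removed. Proteases and their inhibitors stood above the other genes (median log2 change 2.69, camera adjusted p = 4.8e-09, 0.24 if estimated). The inhibitors SPINK7 (266 ± 73.0 against 0 to 3.6 TPM, log2 change 6.95 ± 0.23) and cystatin CST6 (118 ± 33.0 against 0 to 3 TPM, log2 change 5.97 ± 0.24) rose most, with a limma adjusted p of 3.6e-19 or less. The serpin SERPINB1 (37.4 ± 6.91 against 58.3 ± 9.84 TPM, log2 change -0.63 ± 0.13) and cathepsin CTSC (10.1 ± 1.52 against 14.0 ± 1.06 TPM, log2 change -0.49 ± 0.10) fell, with a limma adjusted p of 1.0e-04 or less.

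Of the 26 suprabasal squamous differentiation genes tested, 23 rose, 2 fell and 1 did not pass, with 23 and 2 after rescaling and 21 and 3 with mitochondrial genes removed. The suprabasal genes stood above the other genes (median log2 change 1.78, camera adjusted p = 1.6e-08, 0.24 if estimated, medians 2.08 and 1.35 in batches 1 and 2). Involucrin IVL (446 ± 80.4 against 22.8 ± 17.5 TPM, log2 change 4.82 ± 0.40) and the transcription factor OVOL1 (83.5 ± 6.47 against 6.34 ± 3.14 TPM, log2 change 3.71 ± 0.18) rose most, with a limma adjusted p of 7.2e-12 or less. KRT13 (11.4 ± 2.89 against 67.1 ± 34.6 TPM, log2 change -2.24 ± 0.27) and KRT4 (15.6 ± 2.14 against 71.9 ± 45.5 TPM, log2 change -1.74 ± 0.31) fell, with a limma adjusted p of 1.4e-05 or less. Of the 24 desmosome and tight junction genes tested, 18 rose, 0 fell and 6 did not pass, with 21 and 0 after rescaling and 14 and 5 with mitochondrial genes removed. Genes of the junctions stood above the other genes (median log2 change 0.84, camera adjusted p = 1.6e-06, 0.24 if estimated). DSG1 (188 ± 30.4 against 14.0 ± 10.4 TPM, log2 change 4.16 ± 0.36) and desmocollin DSC2 (258 ± 28.6 against 38.1 ± 12.1 TPM, log2 change 2.81 ± 0.14) rose most, with a limma adjusted p of 1.2e-11 or less. Of the 18 basal keratinocyte genes tested, 6 rose, 8 fell and 4 did not pass, with 8 and 8 after rescaling and 4 and 14 with mitochondrial genes removed. Genes of basal cells were not separated from the other genes (median log2 change -0.074, camera adjusted p = 0.73, 0.86 if estimated, medians -0.12 and -0.071 in batches 1 and 2). The laminin chain LAMB3 (333 ± 17.4 against 95.8 ± 20.2 TPM, log2 change 1.88 ± 0.17, limma adjusted p = 2.1e-11) rose. The nerve growth factor receptor NGFR (0.757 ± 0.341 against 22.4 ± 5.16 TPM, log2 change -3.63 ± 0.26) and KRT15 (110.0 ± 22.8 against 431 ± 39.6 TPM, log2 change -2.05 ± 0.14) fell, with a limma adjusted p of 2.2e-13 or less.

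Of the 30 cell cycle genes tested, 0 rose, 29 fell and 1 did not pass, with 0 and 29 after rescaling and 0 and 30 with mitochondrial genes removed. Cell cycle genes stood below the other genes (median log2 change -2.61, camera adjusted p = 1.5e-15, 0.24 if estimated). CDC20 (3.21 ± 1.10 against 123 ± 48.0 TPM, log2 change -4.91 ± 0.23), an activator of the anaphase-promoting complex, and the mitotic kinesin KIF20A (0.686 ± 0.318 against 47.8 ± 15.7 TPM, log2 change -4.87 ± 0.20) were among the largest falls, with a limma adjusted p of 1.2e-17 or less. So were the kinase HASPIN (0 to 2.5 against 22.6 ± 8.97 TPM, log2 change -4.17 ± 0.30) and the acute phase protein SAA1 (1.54 ± 0.688 against 60.4 ± 25.5 TPM, log2 change -4.41 ± 0.28), with a limma adjusted p of 1.7e-13 or less. RBM12 (listed at 0 in all 7 untreated D11 libraries against 28.9 ± 5.46 TPM, limma adjusted p = 4.4e-07) and GPX2 (listed at 0 in all 7 untreated D11 libraries against 21.0 ± 6.52 TPM, limma adjusted p = 1.3e-09) fell too. The mitochondrial chaperonin HSPE1 (0 to 4.1 TPM in untreated D11 and 8 to 28.6 in D3 libraries, limma adjusted p = 9.7e-06) was also among them. RBM12 and HSPE1 were listed at 0 in all 5 monolayer libraries of batch 2 as well, and at 45.2 to 56.2 and 23.3 to 38.3 TPM in the 5 of batch 1, so a listed 0 can be a failed estimate. Of the 24 hypoxia and glycolysis genes tested, 22 rose, 0 fell and 2 did not pass, with 22 and 0 after rescaling and 19 and 2 with mitochondrial genes removed. Hypoxia and glycolysis genes stood above the other genes (median log2 change 1.85, camera adjusted p = 3.4e-10, 0.24 if estimated). ANKRD37 (181 ± 81.8 against 5.08 ± 1.21 TPM, log2 change 4.81 ± 0.22), an ankyrin repeat gene, and the enolase ENO2 (96.4 ± 35.5 against 6.79 ± 3.28 TPM, log2 change 3.70 ± 0.28) rose most, with a limma adjusted p of 7.4e-13 or less. Of the 21 partial EMT and wound-edge genes tested, 20 rose, 0 fell and 1 did not pass, with 20 and 0 after rescaling and 16 and 0 with mitochondrial genes removed. Wound-edge genes stood above the other genes (median log2 change 1.63, camera adjusted p = 3.0e-08, 0.045 if estimated). The metalloproteinases MMP10 (13.6 ± 1.31 against 0.222 ± 0.120 TPM, log2 change 3.62 ± 0.11) and MMP9 (16.6 ± 2.67 against 0.778 ± 0.632 TPM, log2 change 3.58 ± 0.40) rose most, with a limma adjusted p of 3.8e-09 or less.

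Of the other fixed genes, SPRR3 (4226 ± 534 against 222 ± 184 TPM, log2 change 5.18 ± 0.49), CRNN (216 ± 57.6 against 13.4 ± 10.1 TPM, log2 change 4.33 ± 0.34) and FLG (7.67 ± 1.36 against 1.13 ± 0.505 TPM, log2 change 2.06 ± 0.13) were higher, with a limma adjusted p of 8.4e-11 or less. CISH (31.7 ± 2.10 against 16.2 ± 1.86 TPM, log2 change 0.93 ± 0.10) and TSLP (3.03 ± 1.68 against 0.600 ± 0.433 TPM, log2 change 1.35 ± 0.33) were as well, with a limma adjusted p of 6.4e-04 or less. IL4R (12.3 ± 1.05 against 10.1 ± 1.23 TPM, log2 change 0.28 ± 0.083, limma adjusted p = 0.0038) and SOCS1 (59.3 ± 8.34 against 49.0 ± 14.2 TPM, log2 change 0.31 ± 0.14, limma adjusted p = 0.048) were higher by less as deposited. With mitochondrial genes removed they stood at -0.28, a call lower, and -0.27, which did not pass. SOCS1 stood at 0.15 after quantile normalization and IL4R at 0.17 in batch 2 alone, where they did not pass. Nor did SOCS1 pass in batch 2 alone or without any 1 of D3 libraries 1, 2, 5, 8 or 9 or untreated libraries 1, 2, 3, 5, 6 or 7 (0.23 to 0.33). KRT5 (25874 ± 3507 against 37339.6 ± 5999.9 TPM, log2 change -0.52 ± 0.10), TP63 (11.8 ± 0.802 against 18.0 ± 1.90 TPM, log2 change -0.55 ± 0.10) and ANO1 (0.714 ± 0.146 against 1.61 ± 0.267 TPM, log2 change -0.66 ± 0.17) were lower, with a limma adjusted p of 8.6e-04 or less. With a pseudocount of 5, ANO1 and SOCS1 did not pass. KRT14 (32079 ± 4972 against 32835 ± 5824 TPM, log2 change -0.0015 ± 0.10, limma adjusted p = 0.99) did not pass as deposited and stood at 0.67 after quantile normalization and -0.60 with mitochondrial genes removed. CAPN14 (0.171 ± 0.0488 against 0.144 ± 0.0527 TPM, log2 change 0.030 ± 0.092, limma adjusted p = 0.78) did not pass. Neither did IL13RA2 (0 to 0.1 against 0 to 0.1 TPM, log2 change 0.026 ± 0.079, limma adjusted p = 0.78). CCL26 at 0 to 0.2 TPM and ALOX15 at 0 to 0.1 TPM in untreated D11 spheroids were not tested.

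The mitochondrial share differed between these groups. With mitochondrially encoded genes removed and the rest rescaled, 1663 genes were higher and 8018 lower. Median-of-ratios rescaling gave 4627 higher and 4307 lower. The calls numbered 4656 higher and 3646 lower in batch 1 and 3355 and 5078 in batch 2. Without D3 libraries 4 and 7, which lay with the other batch, 4091 were higher and 4234 lower. Libraries of both groups did not overlap for 4648 genes, against 0.0175% by chance, and of the named genes that passed overlapped for IL4R, KRT4, KRT5 and SOCS1. Further lists above the other genes were unfolded protein and integrated stress response genes (14 rose and 2 fell of 19, 10 and 4 with mitochondrial genes removed, camera adjusted p = 0.0034, 0.52 if estimated, medians 1.49 and 0.85 in batches 1 and 2) and immediate early genes (11 rose and 1 fell of 17, 9 and 5 with mitochondrial genes removed, camera adjusted p = 0.0086, 0.52 if estimated, medians 1.45 and 0.85 in batches 1 and 2). Further lists below them were cholesterol biosynthesis genes (2 rose and 14 fell of 23, 2 and 21 with mitochondrial genes removed, camera adjusted p = 0.0042, 0.44 if estimated) and mitochondrially encoded transcripts (0 rose and 12 fell of 13, camera adjusted p = 2.2e-05, 0.35 if estimated).

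**Figure D3:**
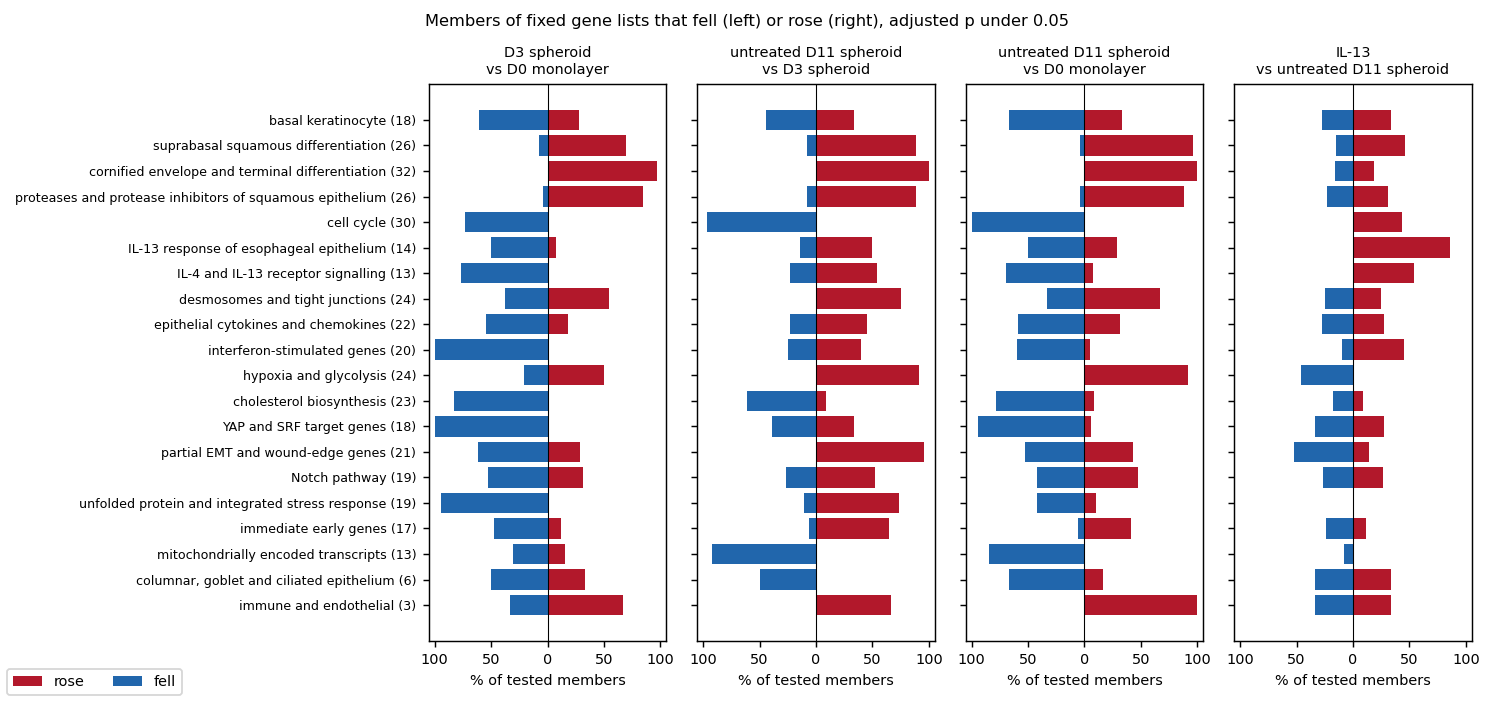
Percent of the tested members of each fixed gene list that rose (red) or fell (blue) at a limma adjusted p under 0.05 in each of the 4 comparisons, with the number of tested members in brackets. In D11 against D3, 32 of 32 cornified envelope genes rose and 29 of 30 cell cycle genes fell. With IL-13 12 of 14 tested IL-13 response genes rose (12 after rescaling), of 20 on the list.

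Over the whole course from monolayer to D11, cornified envelope genes and KRT16 rose most, and a growth factor, a matrix protein and proliferation genes fell most. SPRR1A (24973 ± 3203 against 0 to 5.3 TPM, log2 change 14.19 ± 0.61), SPRR3 (11.97 ± 0.47) and KRT16 (33636 ± 2930.5 against 13.9 ± 7.49 TPM, log2 change 11.39 ± 0.34) led the rises, with a limma adjusted p of 2.3e-19 or less. CSF3 (0 to 3.1 against 506 ± 124 TPM, log2 change -7.98 ± 0.42), THBS1 (27.5 ± 2.27 against 3369.5 ± 429 TPM, log2 change -6.87 ± 0.14) and MKI67 (-6.45 ± 0.19) led the falls, with a limma adjusted p of 3.2e-17 or less. Of 12221 genes, 2561 were higher and 7765 lower in untreated D11 spheroids (n = 7) than in monolayers (n = 10). At 2-fold or more there were 1069 and 2966.

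The other large rises, as log2 change ± SE, were S100A8 (11.35 ± 0.45), CRCT1 (11.20 ± 0.57), LCE3D (10.91 ± 0.69), LCE3E (1861 ± 966 TPM, listed at 0 in all 10 monolayer libraries) and the protease inhibitor SLPI (10.69 ± 0.36), each with a limma adjusted p of 2.6e-15 or less. Of the 32 cornified envelope and terminal differentiation genes tested, 32 rose, 0 fell and 0 did not pass, with 32 and 0 after rescaling and 32 and 0 with mitochondrial genes removed. As a list they stood above the other genes (median log2 change 7.67, camera adjusted p = 1.0e-24, 0.059 if estimated). Above the other genes also stood suprabasal genes (25 rose and 1 fell of 26, camera adjusted p = 5.6e-20, 0.046 if estimated) and proteases and inhibitors (23 rose and 1 fell of 26, camera adjusted p = 3.2e-20, 0.046 if estimated). The other large falls were the decoy receptor TNFRSF6B (-6.21 ± 0.24), CDC20 (-5.87 ± 0.22), FN1 (-5.81 ± 0.17), HASPIN (-5.35 ± 0.29) and the calcium-binding S100A3 (listed at 0 in all 7 untreated D11 libraries against 38.2 ± 3.82 TPM), with a limma adjusted p of 5.6e-17 or less. Of the 18 YAP and SRF target genes tested, 1 rose, 17 fell and 0 did not pass, with 1 and 15 after rescaling and 0 and 18 with mitochondrial genes removed. YAP and SRF targets stood below the other genes (median log2 change -1.69, camera adjusted p = 2.5e-04, 0.057 if estimated). CCN2 (-4.44 ± 0.16) fell with THBS1 (limma adjusted p = 1.8e-21).

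Of the 23 cholesterol biosynthesis genes tested, 2 rose, 18 fell and 3 did not pass, with 4 and 14 after rescaling and 2 and 21 with mitochondrial genes removed. Cholesterol genes stood below the other genes (median log2 change -1.20, camera adjusted p = 0.028, 0.54 if estimated, medians -1.40 and -0.91 in batches 1 and 2). The synthase HMGCS1 (37.2 ± 3.73 against 247 ± 127 TPM, log2 change -2.56 ± 0.17, limma adjusted p = 1.6e-14) fell. The kinase PMVK (19.8 ± 7.12 against 7.74 ± 1.93 TPM, log2 change 1.18 ± 0.15) and the desaturase SC5D (106 ± 17.3 against 58.3 ± 10.1 TPM, log2 change 0.84 ± 0.087) rose, with a limma adjusted p of 1.5e-08 or less. Of the 22 epithelial cytokines and chemokines tested, 7 rose, 13 fell and 2 did not pass, with 8 and 12 after rescaling and 6 and 15 with mitochondrial genes removed. These cytokine genes were not separated from the other genes (median log2 change -1.06, camera adjusted p = 0.68, 0.92 if estimated). The chemokine CXCL1 (1.31 ± 0.372 against 61.0 ± 18.7 TPM, log2 change -4.67 ± 0.16) fell after CSF3, with a limma adjusted p of 3.2e-17 or less. Receptor antagonists IL36RN (79.9 ± 13.8 against 0 to 0.1 TPM, log2 change 6.32 ± 0.30) and IL1RN (149 ± 14.4 against 10.1 ± 2.51 TPM, log2 change 3.82 ± 0.13) rose, with a limma adjusted p of 3.7e-18 or less.

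Of the other fixed genes, KRT5 (0.91 ± 0.094), KRT14 (2.31 ± 0.10), KRT15 (1.92 ± 0.14), KRT13 (3.48 ± 0.27), IVL (8.15 ± 0.39), FLG (3.03 ± 0.12), SPINK7 (7.97 ± 0.22) and CISH (0.84 ± 0.10) were higher at D11, with a limma adjusted p of 5.5e-09 or less. KRT4, CRNN and DSG1 were higher than in the 10 monolayer libraries, all listed at 0, with a limma adjusted p of 1.8e-13 or less. TP63 (-0.76 ± 0.10), ANO1 (-2.48 ± 0.16), IL4R (-1.49 ± 0.081) and IL13RA2 (-0.99 ± 0.077) were lower, with a limma adjusted p of 1.8e-08 or less. SOCS1 (59.3 ± 8.34 against 69.0 ± 9.60 TPM, log2 change -0.21 ± 0.14, limma adjusted p = 0.15) did not pass. It stood at 0.38 after rescaling and -0.79 with mitochondrial genes removed, and passed in both. TSLP (3.03 ± 1.68 against 0 to 5 TPM, log2 change 0.72 ± 0.32, limma adjusted p = 0.04) was called higher, with 2.15 in batch 1 and -0.95 in batch 2. Its call ended with a pseudocount of 5, with mitochondrial genes removed, without the batch term and without any 1 of monolayer libraries 1, 2, 3, 5 or 7 or untreated libraries 1, 2, 3 or 5 (0.55 to 0.68). CAPN14 (0.171 ± 0.0488 against 0.120 ± 0.0422 TPM, log2 change 0.063 ± 0.089, limma adjusted p = 0.52) did not pass as deposited. It stood at 0.14 after rescaling, where it did. CCL26 and ALOX15 were not tested.

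Median-of-ratios rescaling, with a shift of 0.48 in the median log2 change, gave 4916 genes higher and 4902 lower. Of the calls 7463 kept the direction and 838 reversed. Quantile normalization gave 4352 and 5415, and removal of mitochondrial genes 1479 and 9611. The calls numbered 2941 higher and 7173 lower in batch 1 and 2228 and 8058 in batch 2. Libraries of both groups did not overlap for 7170 genes, against 0.0103% by chance, and of the named genes that passed overlapped only for TSLP. The remaining lists above the other genes were hypoxia and glycolysis genes (22 rose and 0 fell of 24, camera adjusted p = 7.5e-16, 0.057 if estimated, medians 1.34 and 2.13 in batches 1 and 2), junction genes (16 rose and 8 fell of 24, 18 and 4 after rescaling, camera adjusted p = 2.8e-07, 0.057 if estimated) and immediate early genes (7 rose and 1 fell of 17, 12 and 1 after rescaling, camera adjusted p = 0.0024, 0.49 if estimated, medians 0.96 and -0.24 in batches 1 and 2). Notch pathway genes (9 rose and 8 fell of 19, camera adjusted p = 0.045, 0.47 if estimated, camera adjusted p = 0.27 after rescaling, medians 0.053 and -0.30 in batches 1 and 2) and immune and endothelial markers (3 rose and 0 fell of 3, camera adjusted p = 0.0024, 0.046 if estimated) were others. With mitochondrial genes removed, 4 immediate early genes rose and 7 fell, and 6 Notch genes rose and 10 fell. The remaining lists below were cell cycle genes (0 rose and 30 fell of 30, camera adjusted p = 3.8e-07, 0.47 if estimated) and mitochondrially encoded transcripts (0 rose and 11 fell of 13, 2 and 9 after rescaling, camera adjusted p = 0.048, 0.69 if estimated). The unfolded protein and integrated stress response list (2 rose and 8 fell of 19, 1 and 8 when adjusted over the list alone, camera adjusted p = 0.68) had a median log2 change of 1.12 in batch 1 and -1.98 in batch 2.

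With IL-13, 12 of 14 tested IL-13 response genes and the esophageal keratins KRT4 and KRT13 rose, and 11 of 21 wound-edge genes fell. CAPN14 (157 ± 38.7 against 0.171 ± 0.0488 TPM, log2 change 7.03 ± 0.10, limma adjusted p = 1.1e-30), a calpain of the esophageal epithelium at chromosome 2, 31173056 to 31233858 (hg38), was among the largest rises. So was TNFAIP6 (247 ± 102 against 0 to 0.1 TPM, log2 change 7.73 ± 0.23, limma adjusted p = 6.3e-22), a hyaluronan-binding protein at chromosome 2, 151357592 to 151380048 (hg38). Corneodesmosin CDSN (13.0 ± 18.7 against 144 ± 100.1 TPM, log2 change -3.73 ± 0.74, limma adjusted p = 1.6e-04) was among the largest falls, with an IL-13 mean of 5.50 TPM without library 1 (50.7 TPM). The late envelope gene LCE1A (0 to 38.6 against 85.5 ± 100.0 TPM, log2 change -3.51 ± 0.61, limma adjusted p = 3.3e-05) was another, with an untreated mean of 50.4 TPM without library 7 (295.8 TPM). Of 12221 genes, 4785 were higher and 1037 lower with IL-13 (n = 6) than without (n = 7). At 2-fold or more they were 383 and 141.

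Of the 14 esophageal IL-13 response genes tested, 12 rose, 0 fell and 2 did not pass, with 12 and 1 after rescaling. The IL-13 response genes stood above the other genes (median log2 change 2.49, camera adjusted p = 1.6e-16, 0.0067 if estimated). Besides CAPN14 and TNFAIP6, the serpin SERPINB4 (619 ± 128 against 4.24 ± 1.41 TPM, log2 change 6.96 ± 0.21) and the chloride channel ANO1 (11.9 ± 2.91 against 0.714 ± 0.146 TPM, log2 change 2.77 ± 0.19) rose, with a limma adjusted p of 4.3e-13 or less. CCL26, the eosinophil chemoattractant eotaxin-3, measured 0.4 to 2.2 TPM with IL-13 and 0 to 0.2 TPM without. The lipoxygenase ALOX15 measured 0 to 0.5 TPM and 0 to 0.1 TPM, and both stayed below the filter. Of the 13 genes of IL-4 and IL-13 receptor signalling tested, 7 rose, 0 fell and 6 did not pass, with 7 and 3 after rescaling. Receptor signalling genes were not separated from the other genes (median log2 change 0.29, camera adjusted p = 0.069, 0.74 if estimated), and stood above after rescaling (camera adjusted p = 0.036). The feedback inhibitors CISH (192 ± 39.9 against 31.7 ± 2.10 TPM, log2 change 2.53 ± 0.12) and SOCS1 (192 ± 26.7 against 59.3 ± 8.34 TPM, log2 change 1.68 ± 0.16) rose most, with a limma adjusted p of 7.0e-10 or less. IL4R (11.0 ± 1.46 against 12.3 ± 1.05 TPM, log2 change -0.13 ± 0.092, limma adjusted p = 0.24) did not pass as deposited. It stood at -0.37 after rescaling, where it did, as after quantile normalization. IL13RA2 (0 to 0.1 against 0 to 0.1 TPM, log2 change 0.065 ± 0.088, limma adjusted p = 0.56) did not pass.

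Of the 26 suprabasal squamous differentiation genes tested, 12 rose, 4 fell and 10 did not pass, with 10 and 7 after rescaling. Suprabasal differentiation genes were not separated from the other genes (median log2 change 0.26, camera adjusted p = 0.087, 0.74 if estimated), and stood above after rescaling (camera adjusted p = 0.018). KRT4 (761 ± 194 against 15.6 ± 2.14 TPM, log2 change 5.59 ± 0.35) and KRT13 (219.7 ± 63.0 against 11.4 ± 2.89 TPM, log2 change 4.15 ± 0.31) rose most, with a limma adjusted p of 3.7e-12 or less. IVL (87.6 ± 50.5 against 446 ± 80.4 TPM, log2 change -2.33 ± 0.45) and transglutaminase TGM1 (183 ± 35.1 against 344 ± 46.5 TPM, log2 change -0.81 ± 0.32) fell, with a limma adjusted p of 0.04 or less. TGM1 did not pass without any 1 of untreated libraries 1, 2, 3 or 5 or IL-13 libraries 2, 3, 5 or 6 (-0.82 to -0.71). Of the 32 cornified envelope and terminal differentiation genes tested, 6 rose, 5 fell and 21 did not pass, with 5 and 5 after rescaling. Terminal differentiation genes stood below the other genes (median log2 change -0.38, camera adjusted p = 0.0035, 0.74 if estimated), and were not separated after rescaling (camera adjusted p = 0.33). CRNN (1229.7 ± 276 against 216 ± 57.6 TPM, log2 change 2.60 ± 0.38), SPRR2F (23.7 ± 13.3 against 5.27 ± 2.90 TPM, log2 change 2.00 ± 0.38) and SPRR3 (12973 ± 2281 against 4226 ± 534 TPM, log2 change 1.80 ± 0.54) rose, with a limma adjusted p of 0.0074 or less. LORICRIN (0 to 3.7 against 5.57 ± 2.37 TPM, log2 change -1.73 ± 0.27), LCE1F (4.65 ± 7.18 against 46.3 ± 46.0 TPM, log2 change -2.96 ± 0.48), C1orf68 (0 to 3.9 against 20.3 ± 18.3 TPM, log2 change -3.28 ± 0.40) and FLG (2.88 ± 0.842 against 7.67 ± 1.36 TPM, log2 change -1.13 ± 0.14) fell, with a limma adjusted p of 1.2e-05 or less. Means of LCE1F were 1.74 TPM without IL-13 library 1 (19.2 TPM) and 30.6 TPM without untreated library 7 (140.1 TPM).

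Of the 26 squamous proteases and protease inhibitors tested, 8 rose, 6 fell and 12 did not pass, with 8 and 7 when adjusted over the list alone, 6 and 8 after rescaling. Protease genes were not separated from the other genes (median log2 change 0.082, camera adjusted p = 0.65, 0.93 if estimated). CAPN14 and SERPINB4 rose most, and kallikrein KLK5 (47.7 ± 10.7 against 185 ± 10.9 TPM, log2 change -1.93 ± 0.33) and CST6 (42.3 ± 15.4 against 118 ± 33.0 TPM, log2 change -1.25 ± 0.27) fell, with a limma adjusted p of 3.8e-04 or less. With a pseudocount of 0.1, CST6 and TGM1 did not pass. SPINK7 (177 ± 93.3 against 266 ± 73.0 TPM, log2 change -0.51 ± 0.26, limma adjusted p = 0.10) did not pass as deposited. It stood at -0.77 after rescaling and -0.74 without IL-13 library 1, where it did, as with a pseudocount of 5. Of the 24 desmosome and tight junction genes tested, 6 rose, 6 fell and 12 did not pass, with 3 and 12 after rescaling. Desmosome and tight junction genes stood below the other genes (median log2 change -0.026, camera adjusted p = 0.024, 0.74 if estimated). The claudins CLDN7 (129 ± 32.8 against 51.6 ± 20.0 TPM, log2 change 1.41 ± 0.28) and CLDN23 (2.22 ± 0.937 against 0 to 2.2 TPM, log2 change 0.78 ± 0.23) rose, with a limma adjusted p of 0.0059 or less. DSG1 (59.9 ± 8.11 against 188 ± 30.4 TPM, log2 change -1.54 ± 0.40) and DSC2 (114 ± 8.61 against 258 ± 28.6 TPM, log2 change -1.14 ± 0.16) fell, with a limma adjusted p of 0.0022 or less. Of the 18 basal keratinocyte genes tested, 6 rose, 5 fell and 7 did not pass, with 7 and 5 when adjusted over the list alone, 5 and 7 after rescaling. Basal keratinocyte genes were not separated from the other genes (median log2 change 0.14, camera adjusted p = 0.31, 0.74 if estimated). SOX2 (139 ± 18.9 against 46.0 ± 8.44 TPM, log2 change 1.46 ± 0.14), KRT15 (255 ± 55.2 against 110.0 ± 22.8 TPM, log2 change 1.06 ± 0.16) and TP63 (21.0 ± 3.51 against 11.8 ± 0.802 TPM, log2 change 0.82 ± 0.11) were higher, with a limma adjusted p of 4.7e-06 or less. The laminin chain LAMA3 (24.2 ± 3.86 against 45.0 ± 3.39 TPM, log2 change -0.84 ± 0.11, limma adjusted p = 4.6e-07) was lower. KRT5 (27049 ± 2942 against 25874 ± 3507 TPM, log2 change 0.083 ± 0.11, limma adjusted p = 0.55) did not pass as deposited. It stood at 0.55 after quantile normalization, where it did. KRT14 (30086 ± 6084 against 32079 ± 4972 TPM, log2 change -0.044 ± 0.11, limma adjusted p = 0.76) did not pass.

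Of the 21 partial EMT and wound-edge genes tested, 3 rose, 11 fell and 7 did not pass, with 2 and 12 after rescaling. Genes of the wound edge stood below the other genes (median log2 change -0.38, camera adjusted p = 5.7e-10, 0.0067 if estimated). MMP10 (0.883 ± 0.387 against 13.6 ± 1.31 TPM, log2 change -2.88 ± 0.12) and MMP1 (1.82 ± 0.581 against 12.7 ± 2.40 TPM, log2 change -2.35 ± 0.21) fell most, with a limma adjusted p of 3.1e-10 or less. Integrin ITGAV (19.6 ± 3.59 against 11.7 ± 1.31 TPM, log2 change 0.76 ± 0.15) and urokinase PLAU (339 ± 64.9 against 215 ± 38.3 TPM, log2 change 0.74 ± 0.20) rose, with a limma adjusted p of 0.0037 or less. Of the 24 hypoxia and glycolysis genes tested, 0 rose, 11 fell and 13 did not pass, with 0 and 16 after rescaling. Glycolysis and hypoxia genes stood below the other genes (median log2 change -0.43, camera adjusted p = 1.7e-09, 0.42 if estimated). Hexokinase HK2 (57.8 ± 36.8 against 212 ± 56.2 TPM, log2 change -1.93 ± 0.22) and ENO2 (48.3 ± 33.6 against 96.4 ± 35.5 TPM, log2 change -1.10 ± 0.31) fell most, with a limma adjusted p of 0.0047 or less. Of the 22 epithelial cytokines and chemokines tested, 6 rose, 6 fell and 10 did not pass, with 6 and 7 after rescaling. Cytokines and chemokines were not separated from the other genes (median log2 change -0.025, camera adjusted p = 0.14, 0.74 if estimated). Interleukin 36 alpha IL36A (63.5 ± 23.4 against 2.03 ± 1.42 TPM, log2 change 4.45 ± 0.27) and the chemokine CXCL16 (37.5 ± 6.51 against 14.6 ± 2.60 TPM, log2 change 1.45 ± 0.22) rose most, with a limma adjusted p of 4.6e-06 or less. TNF (1.55 ± 0.647 against 8.74 ± 4.98 TPM, log2 change -1.49 ± 0.40) and CSF2 (0 to 0.3 against 2.50 ± 1.14 TPM, log2 change -1.35 ± 0.27) fell most, with a limma adjusted p of 0.0033 or less, but not with a pseudocount of 5. TSLP (2.95 ± 1.01 against 3.03 ± 1.68 TPM, log2 change 0.20 ± 0.37, limma adjusted p = 0.68) did not pass. Of the 30 cell cycle genes tested, 13 rose, 0 fell and 17 did not pass, with 8 and 1 after rescaling. Cycling genes were not separated from the other genes (median log2 change 0.45, camera adjusted p = 0.55, 0.93 if estimated). BIRC5 (6.43 ± 2.61 against 2.27 ± 0.468 TPM, log2 change 0.96 ± 0.24) and MKI67 (3.32 ± 1.38 against 1.01 ± 0.267 TPM, log2 change 0.89 ± 0.22) rose most, with a limma adjusted p of 0.0019 or less. MKI67 did not pass with a pseudocount of 5. Among other large changes, LYPD2 (169 ± 7.98 against 6.47 ± 2.07 TPM, log2 change 4.66 ± 0.20), a Ly6 family member, and the membrane mucin MUC1 (52.9 ± 9.56 against 1.20 ± 0.351 TPM, log2 change 4.62 ± 0.17) rose, with a limma adjusted p of 4.9e-18 or less. Interferon kappa IFNK (0 to 0.6 against 28.1 ± 9.91 TPM, log2 change -4.72 ± 0.13), the matrix protease ADAMTS1 (10.7 ± 7.42 against 94.2 ± 12.4 TPM, log2 change -3.30 ± 0.23) and DEPP1 (18.1 ± 10.7 against 133 ± 42.6 TPM, log2 change -2.87 ± 0.28) fell, with a limma adjusted p of 1.3e-09 or less.

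**Figure D4:**
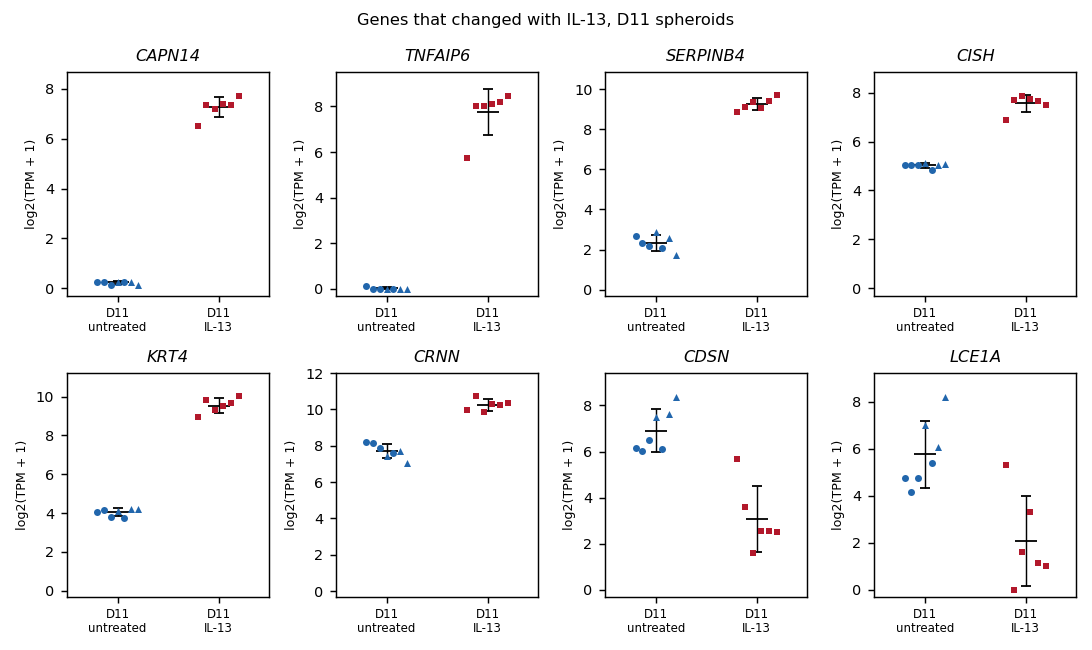
Log2(TPM + 1) of 8 genes in each D11 library without and with IL-13, 1 point per library (circles batch 1, triangles batch 2, squares IL-13 libraries whose batch was not matched), with the mean ± SD as a bar. CAPN14, TNFAIP6, SERPINB4, CISH, KRT4, CRNN and CDSN did not overlap between the groups, and LCE1A did.

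Median-of-ratios rescaling moved the median log2 change of all genes by -0.19. It gave 2362 genes higher and 2515 lower, with 3399 calls in the same direction and 0 reversed. Quantile normalization gave 2289 and 2536. IL-13 columns match no single sample, so no within-batch value is given. Against untreated batch 1 libraries alone, 3134 genes were higher and 972 lower, and against batch 2 ones 5199 and 860. Without IL-13 library 1, which lay apart, there were 6130 and 1027. Libraries of both groups did not overlap for 1674 genes, against 0.117% by chance, and of the named genes that passed overlapped for BIRC5, CLDN23, CLDN7, CSF2, CST6, ENO2, LCE1A, LCE1F, LORICRIN, MKI67 and PLAU.

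Other lists below the remaining genes with IL-13 were cholesterol biosynthesis genes (2 rose and 4 fell of 23, 2 and 11 after rescaling, camera adjusted p = 0.005, 0.74 if estimated) and immediate early genes (2 rose and 4 fell of 17, camera adjusted p = 0.014, 0.74 if estimated, camera adjusted p = 0.078 after rescaling). Mitochondrially encoded transcripts (0 rose and 1 fell of 13, 0 and 6 after rescaling, camera adjusted p = 0.032, 0.74 if estimated) were another. The immediate early list had a median log2 change of 0.0059 and a mean of -0.070. Lists not separated from the other genes were YAP and SRF target genes (5 rose and 6 fell of 18, 2 and 7 after rescaling, camera adjusted p = 0.087, 0.74 if estimated), interferon-stimulated genes (9 rose and 2 fell of 20, camera adjusted p = 0.99, 1.00 if estimated) and Notch pathway genes (5 rose and 5 fell of 19, camera adjusted p = 0.31, 0.74 if estimated). Stress response genes (0 rose and 0 fell of 19, 0 and 3 after rescaling, camera adjusted p = 0.19, 0.74 if estimated), columnar epithelium markers (2 rose and 2 fell of 6, camera adjusted p = 0.65, 0.74 if estimated) and immune and endothelial markers (1 rose and 1 fell of 3, camera adjusted p = 0.65, 0.74 if estimated) were others. Adjusted over the list alone, 6 YAP and SRF targets rose and 6 fell. The only fibroblast marker tested, COL1A1, had a log2 change of -0.86 ± 0.24 (limma adjusted p = 0.0038).

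The IL-13 change was set against that from D3 to D11. So that no untreated library entered both, genes were called with odd-numbered ones and the IL-13 change measured against even-numbered ones. The 3978 genes that rose had a median IL-13 change of 0.014, below the all-gene median of 0.16, and the 3981 that fell 0.28. Both lean on library 2, the only even one of batch 1, the batch of most IL-13 samples. With the libraries exchanged the medians were -0.057 and 0.32, and after rescaling -0.14 and 0.13 against an all-gene median of 0.00087. Across genes, which are not independent replicates, the changes correlated at r = -0.34 and -0.42 in these splits. With all untreated libraries in both, r was -0.42 and the covariance -0.17, against -0.066 and -0.0086 for simulated unchanged groups. Deviations shared by untreated libraries stay in both splits and were not tested.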

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

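Chosen only after the results were seen were the test of the mitochondrial share, the gene weights of component 1, the slopes of IL-13 library 1 against untreated libraries of single batches, and the exchange of batch labels of D3 libraries 4 and 7. Single libraries lay far from the rest of their group, by Dixon's test, in 29 of 270 gene and group combinations, and chance gives about 1 in 20.

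The change differed between the 2 experiments, by limma's interaction test, for 4430 genes in D3 spheroids against monolayers, 756 in untreated D11 against D3 spheroids and 4937 in untreated D11 spheroids against monolayers. On component 1 of the libraries D3 libraries 4 and 7 lay with the other batch. On 2399 genes that differed between batches alike in monolayers and untreated D11 spheroids, library 4 (-2.89) exceeded library 7 (-3.03) by 104% of the gap between the other D3 batches, as exchanged labels would give. The other D3 libraries overlapped on this score (-3.10 to -2.84 in batch 1, -2.88 to -2.85 in batch 2), which keeps an exchange open. Different progress of differentiation stays open too. Library 4 minus its batch mates correlated with the untreated D11 minus monolayer change at r = 0.620 across genes and library 7 at -0.731. Gene weights of component 1 followed that change (r = 0.988), so this restated their place on it and decided nothing. With the labels exchanged, the change from D3 to D11 differed between batches for 3871 genes.

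More genes were lower than higher in D3 spheroids than in monolayers. The mitochondrial share was 47.8 ± 7.27% in D3 spheroids and 47.6 ± 2.00% in monolayers. What it left to other genes moved by -0.016 ± 0.070 (SE) on the log2 scale, against a median change of -0.44, which argues against it as the main cause. The 446 genes that rose at 2-fold or more under both scalings went from 3.84 ± 0.199% to 15.2 ± 4.34% of the TPM. The share left to other genes moved by -0.18 on the log2 scale, 41.3% of that median, so composition could account for part of it and stays open. The RNA content of the cells was not measured, and TPM, a share of each library's own total, cannot show it.

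IL-13 library 1 gave 14 of the single values, with TPM of ANO1 6.1 (12.6 to 13.9), BIRC5 1.5 (5.9 to 8.6), CISH 117.8 (182.1 to 231.9), CLDN7 67.9 (118.7 to 157.9), IL36A 23.1 (56 to 88.4), KLK5 68.7 (41 to 49.1), KRT13 100.1 (205.4 to 278), LCE1F 19.2 (1 to 3.3), MKI67 0.8 (3.3 to 5), MUC1 34.7 (50.6 to 61.1), PLAU 209.7 (347.9 to 384.6), SPINK7 361.2 (113.4 to 175.2), TNFAIP6 52.3 (257.5 to 352.9) and TP63 14.4 (20.5 to 24.6) in the other 5 libraries. On the batch genes it scored -2.38, against -3.07 to -2.92 in the others, which is 141% of the gap between untreated batches and is consistent with a library of the second experiment. A weaker response may also hold, since its changes followed those of the other libraries with a slope of 0.555, against 1.01 to 1.09 for each of them. The slope was 0.57 against untreated batch 1 and 0.68 against untreated batch 2, so both explanations stay open together.

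Other single values, in TPM with the range of the other libraries of the group, were IFNK 0.6 in library 3 (0 in the others) among IL-13 libraries, ALOX15 0.2 in library 6 (0 to 0.1), CXCL14 0.2 in library 4 (0 to 0.1), FLG 0.2 in library 2 (0 to 0.1) and SPRR3 0.7 in library 9 (0 to 0.3) among monolayers and F3 16.6 in library 9 (22.4 to 29.5) among D3 spheroids. Among untreated D11 spheroids they were ALOX15 0.1 in library 7 (0 in the others), CISH 27.4 in library 5 (31.5 to 34), CSF2 0.3 in library 2 (1.7 to 3.5), HSPE1 4.1 in library 7 (0 in the others), IL1RN 121.1 in library 5 (146.4 to 168.2), KLK5 163.2 in library 2 (181.7 to 196.2), KRT16 27751.6 in library 2 (32280.5 to 35875.6), THBS1 22.9 in library 1 (27.4 to 30.3) and TNFAIP6 0.1 in library 1 (0 in the others).

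Of 100 splits of the same libraries each, 1, 1 and 1 (the real ones) called as many genes as observed in the first 3 comparisons. These were D3 against monolayer (9895, highest other 6251), D11 against D3 (8472 and 7570) and D11 against monolayer (10326 and 9199). For IL-13, 2 splits did, the real one included (5822 genes). The other (6574 genes) exchanged IL-13 library 1, which lay apart by batch or by response, with untreated library 3. Splits other than the real ones called a median of 0, and the highest largely kept the real groups. Without IL-13 library 1 the real comparison called 6130 genes higher and 1027 lower. Such splits are arbitrary groupings and treat libraries as independent, although from 2 experiments, and cannot exclude chance between experiments.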

How the results depend on the processing

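Chosen only after seeing the data were the alternatives that leave out D3 libraries 4 and 7 or exchange their batch labels, those with cell means of group and batch, those with untreated libraries of a single batch, the rescaled split, and for named genes removal of mitochondrial genes and each library left out (IL-13 library 1 for lists too). For IL-13 single-batch fits and batch interactions were not run, as its columns match no single sample. Depth is unknown, so its effect could not be assessed.

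Of the log2 changes of named genes under alternatives other than single libraries left out, save IL-13 library 1, 1465 kept direction and side of the threshold, 21 lost and 12 gained the call and 13 changed sign. Numbers of genes higher and lower stayed within 1.5 times under both pseudocounts (those at 2-fold or more did not), both filters, single batches, no batch term, library weights and fits of only the groups compared. They did not under the following. Median-of-ratios scaling gave 4064 and 4052 in D3 against monolayer, 4916 and 4902 in D11 against monolayer and 2362 and 2515 with IL-13. Quantile normalization gave 3706 and 4421 in the first of these, 2289 and 2536 with IL-13, and 4352 higher in D11 against monolayer. Removal of mitochondrial genes gave 1663 and 8018 in D11 against D3 and 1479 higher in D11 against monolayer. Median-of-ratios scaling and removal shift all genes by construction, and for quantile normalization the cause was not tested. With untreated batch 1 alone, 3134 genes were higher with IL-13. With batch labels of D3 libraries 4 and 7 exchanged, 3871 genes differed between batches from D3 to D11. Neither cause was tested. Without each IL-13 or untreated library in turn, 4101 to 6130 genes were higher and 938 to 1064 lower with IL-13.

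Changing only the correlation, to an estimate, lowered the lists called per comparison from 10, 11, 12 and 8 to 1, 1, 3 and 2. Those that held were YAP and SRF targets at D3, wound-edge genes from D3 to D11, suprabasal, protease and immune and endothelial lists in D11 against monolayer, and IL-13 response and wound-edge genes with IL-13. Fry called 18 lists at D3, where it compares a list with no other genes, and quantile normalization 5 with IL-13, for which the cause was not tested.

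Signs reversed for ANXA1 (0.36 with median-of-ratios and 0.12 with quantile scaling), TP63 (0.30 and 0.25), CISH (0.42 and 0.39) and SOCS1 (0.0060) in D3 against monolayer, SOCS1 in D11 against monolayer (0.38), and with quantile scaling KRT14 in D11 against D3 (0.67). With mitochondrial genes removed IL4R (-0.28) and SOCS1 (-0.27) did so in D11 against D3. The shift of all genes gives those with median-of-ratios and removal, and for quantile scaling the cause was not tested. TP63 stood at 0.047 at D3 in batch 1 only, and TSLP at -0.95 in D11 against monolayer in batch 2 only, and the cause was not tested. The median IL-13 change of genes that rose from D3 to D11 was -0.057 with sets from even-numbered libraries, -0.0066 with all untreated libraries in both comparisons and -0.14 in the rescaled split, below the all-gene median each time, and the cause was not tested.

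Same-numbered libraries did not deviate together (r from -0.44 to 0.36 over 9 pairs of monolayer and D3, -0.16 to 0.16 over 7 of D3 and D11, -0.022 to 0.056 over 7 of monolayer and D11), so the numbers do not pair them. A fit with the number as a replicate block called 1551 and 8376 genes higher and lower in D3 against monolayer, 4085 and 4488 in D11 against D3 and 2519 and 7758 in D11 against monolayer.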

Other observations

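The gene families and genes below were chosen after their values were seen. With IL-13, of 10 LCE1 and LCE2 genes 0 rose and 9 fell (median log2 change -1.82), and 0 rose and 9 fell after median-of-ratios rescaling. None of the 3 LCE3 genes passed the limma test (median 0.31), and the families' difference was not tested. The metallothionein MT2A (234 ± 49.0 against 1517 ± 127 TPM, log2 change -2.83 ± 0.18, limma adjusted p = 7.2e-14) fell, while MT1X (1645 ± 319 against 1852 ± 338 TPM, log2 change -0.18 ± 0.16, limma adjusted p = 0.37) did not pass, and of 5 metallothioneins 2 fell, 3 after rescaling. Of 11 kallikreins KLK12, KLK13 and KLK7 rose and KLK14, KLK5, KLK6, KLK8 and KLK9 fell, with 1 and 5 after rescaling.

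The mucin MUC21 (191 ± 39.0 against 10.7 ± 3.49 TPM, log2 change 4.11 ± 0.30, limma adjusted p = 2.6e-12) rose, 1 of 3 that did among 4 mucins, as did SERPINB3 (1839.5 ± 285 against 211 ± 44.2 TPM, log2 change 3.27 ± 0.39, limma adjusted p = 7.7e-08), a close paralog of SERPINB4, the water channel AQP3 (431 ± 79.2 against 129.7 ± 22.0 TPM, log2 change 1.59 ± 0.20, limma adjusted p = 1.7e-07) and the claudin CLDN5 (9.50 ± 3.20 against 0 to 0.3 TPM, log2 change 3.24 ± 0.14, limma adjusted p = 2.4e-18). In all, 6 rose and 3 fell of 13 SERPINB genes (4 fell after rescaling), 1 and 1 of 3 aquaporins and 5 and 3 of 14 claudins (4 fell after rescaling). The 4 named kept their direction after rescaling (log2 change 3.88, 3.01, 1.34 and 3.19).

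There were 104 genes listed at 0 in all libraries of a batch of 1 group and at 10 TPM or more in another, and for 6 of them both lay in the same group. FEN1 measured 115.8 to 145.1 TPM in 5 monolayers of batch 1 and 0.3 to 1.9 TPM in 5 of batch 2.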
